A study of Eucalyptus grandis
Pisolithus microcarpus and Pisolithus microcarpus and Eucalyptus grandis with 43 samples.

How the data were processed

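Poly-A libraries were sequenced in 150 bp paired-end mode, per the labels' protocols, from root tips of Eucalyptus grandis seedlings 2 weeks after contact with Pisolithus microcarpus, from free-living mycelium of the fungus and from control roots, on a half-strength medium with 0.1 g of glucose per litre. The authors deposited 2 tables of raw read counts per gene model, 1 for the fungus and 1 for the plant, whose values are whole numbers with totals that differ between libraries. The submitters' processing notes name DESeq2, with no role. The aligner, the counting tool and the genome builds are not given in the sources used here, nor is it stated how reads of near-identical gene copies were assigned, so counts of such genes are uncertain. The plant table holds 0 gene models without a count in any library, with a lowest total per model of 2, and the fungal table holds 49. Each column was matched to its sample by title, and the 3 control roots by the replicate number in their description. The 6 samples of a further isolate, MH-615, had no column in these tables and are not analysed here, so averages run over 5 isolates instead of the 6 planned.

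Counts were analysed as deposited. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, with limma 3.58.1), with TMM scaling, genes kept by filterByExpr on the groups, robust dispersions and 1 coefficient per group, all libraries of a table in 1 fit so that small groups share an estimate of spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, for each isolate, for the mean over isolates with equal weight, for the interaction of isolate and tissue, and between isolates within a tissue. The adjusted p-values measure the spread between samples that the labels call biological replicates. No pair of replicates agreed within counting noise: the chi-square per degree of freedom of their counts was at least 1.98 in the fungal and 10.8 in the plant table. The fungal share of counts was the fungal total divided by the sum of the fungal and plant totals of a library. Variance shares were computed on log2 CPM with a prior count of 2. Floors for genes at 0 are 3 counts over the total of the group concerned.

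The rule for naming genes, set before the data were examined, asked for annotated genes, with a reduced form in case identifiers could not be paired with names. The reduced form was used: the 2 largest rises and the 2 largest falls of each average comparison among genes with an adjusted p under 0.05, the same sign of change in every isolate analysed and a mean log2 CPM of at least 1. Identifiers were not paired with names, since 0 of the 26635 plant identifiers matched the RefSeq gene table used here and no table was at hand for the fungus. The planned gene lists select genes by words of an annotation and were therefore not run. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter or a mean count of 10, a minimum absolute log2 fold change of 1, a replicate block, only the 2 groups compared, thinning of fungal libraries to 164614 counts, and leaving out each library. The replicate numbers in titles and descriptions differ in 2 groups, and both were tried as a block.

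The procedure was tested on simulated data with 200 changed genes per table. With all isolates changed, the average comparison recovered 88% of 2-fold and 96% of 4-fold changes among 10667 fungal genes, and 10% and 44% among 24351 plant genes, with 9 and 2 false calls. The control roots were simulated once more without any effect in 20 data sets, for the comparisons that share them. The depth of the Wil3 mycelium limits that isolate: 42% of 2-fold changes were recovered in its root tip comparison, against 69% in MW3.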

Results

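The libraries measured gene expression in an ectomycorrhiza, the sheathed root tip that a soil fungus forms with a tree. The tree was Eucalyptus grandis and the fungus was Pisolithus microcarpus, represented here by 5 isolates named Wil3, MW3, SI-14, R10 and MD-06. For each isolate there were root tips collected 2 weeks after contact and free-living mycelium grown without a plant, and 3 libraries of control roots grown without a fungus served the plant side. The root tips of SI-14 and the mycelium of every isolate had 3 libraries each, and the root tips of the other isolates had 4. The 19 root tip libraries entered both tables, since their reads come from both organisms. No mycelium entered the plant table and no control root the fungal table. Fungal reads counted on plant models, or the reverse, could therefore not be checked for. The fungal table held 11205 gene models in 34 libraries and that of the plant 26635 gene models in 22 libraries. Fungal totals ran from 1400217 to 7302409 counts in root tips and from 13640472 to 32510639 in the mycelium of 4 isolates. The 3 mycelium libraries of Wil3 were far shallower, with 164614 to 280933 counts. Plant totals ran from 6865235 to 14032426 counts in root tips and from 7564438 to 14233329 in control roots. The labels call the samples biological replicates. The files pair no gene model with a name, so genes are given by identifier.

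The first question was how much of the sequenced RNA of a root tip came from the fungus. The fungal share of counts differed between isolates and was highest with SI-14, at 48.3% ± 3.11 (SD, n = 3). It was lowest with MW3, at 15.6% ± 4.89 (SD, n = 4), and in between with Wil3 (35.2% ± 4.88, n = 4), MD-06 (35.1% ± 2.66, n = 4) and R10 (30.0% ± 3.62, n = 4). A permutation test of the between-isolate F on the logit share over the 19 libraries gave p = 1e-05, the smallest value that 100000 resamples can give. In exact two-sided permutation tests of the 10 pairs of isolates, every pair with MW3 or SI-14 in it reached the smallest p that 4 against 4 or 4 against 3 libraries allow, 0.0286, which is 0.0408 after Benjamini-Hochberg adjustment. Wil3, R10 and MD-06 did not separate from each other in these tests, with exact p from 0.0857 to 1. The lowest single library was MW3 replicate 1, at 9.07% (95% Wilson interval 9.06 to 9.09), and the highest was SI-14 replicate 3, at 51.5% (51.5 to 51.6). These intervals cover counting error only, and the share is one of counted reads, not of tissue mass. Reads of all isolates were counted on 1 set of fungal gene models, so differences in sequence match can also enter the share.

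**Figure D1:**
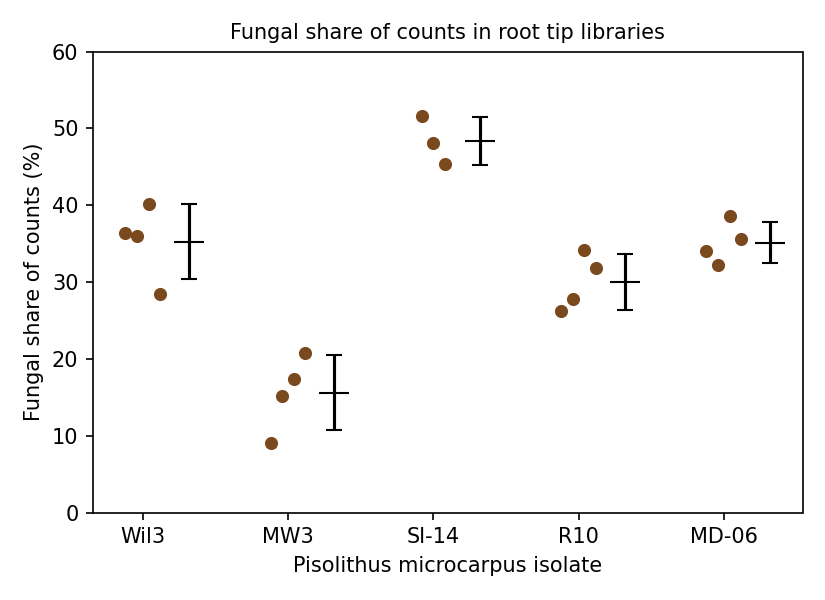
Fungal share of counts (%) in each of the 19 root tip libraries by isolate. Points are libraries, and the dash with its bar gives the mean and SD of each isolate, from 15.6% with MW3 to 48.3% with SI-14.

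Root tips were next compared with the free-living mycelium of the same isolates, averaged over the 5 isolates with equal weight, for the mean fungal response to the host. Of 10667 fungal genes tested, 2573 were higher and 1684 lower in root tips (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most of these differences were small: 476 higher and 159 lower genes had a fitted log2 fold change of at least 1 in size. The largest rise belonged to the model with protein identifier 689733, at 40.6 ± 47.0 CPM in root tips (SD, n = 19) and 0.37 ± 0.28 CPM in mycelium (SD, n = 15). Its lowest root tip library, at 2.99 CPM, lay above its highest mycelium library, at 0.82 CPM (log2 fold change 7.06, SE 0.62, adjusted p = 3.03e-09). The model 683137 rose from 1.11 ± 0.66 to 81.3 ± 121 CPM (log2 fold change 6.23, SE 0.60, adjusted p = 1.46e-08), with group means in root tips between 9.28 CPM for MW3 and 260 CPM for SI-14. Both models had 0 counts in the Wil3 mycelium, where the depth allows up to 4.64 CPM, so their fitted folds depend on the prior count there, and the log2 fold changes were 6.11 and 5.19 without Wil3, 5.95 and 5.08 with DESeq2, and 4.64 and 5.22 with every library thinned to 164614 counts. The largest falls were those of the models 199714 (log2 fold change -3.15, SE 0.23, adjusted p = 1.44e-11) and 4343739 (log2 fold change -2.74, SE 0.29, adjusted p = 2.60e-08). The model 199714 went from 320 ± 142 CPM in mycelium (SD, n = 15) to 51.7 ± 66.7 CPM in root tips (SD, n = 19) and passed the test in each of the 5 isolates. The model 4343739 went from 496 ± 560 to 121 ± 168 CPM and passed it in 3 isolates. In the thinned libraries the average comparison called 828 higher and 881 lower genes, so the balance of directions turned.

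Taken isolate by isolate, the number of fungal genes called was highest in MW3. In MW3 root tips 2614 fungal genes were higher and 1855 lower than in MW3 mycelium, 41.9% of those tested. R10 had 1027 higher and 854 lower genes, SI-14 606 and 596, Wil3 698 and 450, and MD-06 534 and 384. The median size of the called changes was larger in Wil3, at 1.12 on the log2 scale, than in MW3, at 0.91. With the shallow Wil3 mycelium, 42% of simulated 2-fold changes were recovered, against 69% in MW3. Small changes were thus called less often in Wil3, and the 2 medians do not compare the size of the responses. Genes called in every isolate came to 57 higher and 32 lower. Independent lists of the sizes called in the 5 isolates would share 0.047 and 0.013. These figures take all genes as equally likely to be called, so they set no level for chance. When Wil3 was left out, genes called in each of the other 4 isolates came to 134 higher and 148 lower. A further 411 genes were called higher in one isolate and lower in another. Across genes, the fold changes of 2 isolates correlated with Pearson's r of 0.12 to 0.45, with the highest value for R10 and MD-06 (0.45) and values of 0.12 and 0.17 for MW3 against R10 and MD-06. Genes are not independent replicates, so these correlations carry no p. Thinned to equal depth, MW3 still had the most calls, 1410 against 551 for Wil3, 432 for R10, 340 for SI-14 and 152 for MD-06, and the genes called in every isolate came to 22 higher and 1 lower. The balance of directions depended on the fit: lower calls outnumbered higher ones in MW3 (643 higher, 767 lower), R10 (178 and 254) and SI-14 (153 and 187) when thinned, and in each of the 5 isolates when only the 2 groups compared were fitted. That fit called 183 genes in Wil3, 1925 in SI-14 and 3463 in R10, and DESeq2 called 1485 in MD-06. Single libraries moved these counts by more than 1.5 times, except in MW3. The count of Wil3 fell to 667, 733 and 732 without mycelium replicate 1, 2 or 3, and that of MD-06 to 465, 474 and 533 without mycelium replicate 1, 2 or 3 and to 560 without root tip replicate 1. That of SI-14 fell to 721 and 494 without mycelium replicate 2 or 3 and to 681 and 707 without root tip replicate 1 or 3, and that of R10 to 1142 and 1026 without mycelium replicate 1 or 2. The count of genes lower in every isolate fell to 17 or 21 without Wil3 mycelium replicate 1, SI-14 mycelium replicate 3, MD-06 mycelium replicate 1 or 3, or MD-06 root tip replicate 1 or 4.

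**Figure D2:**
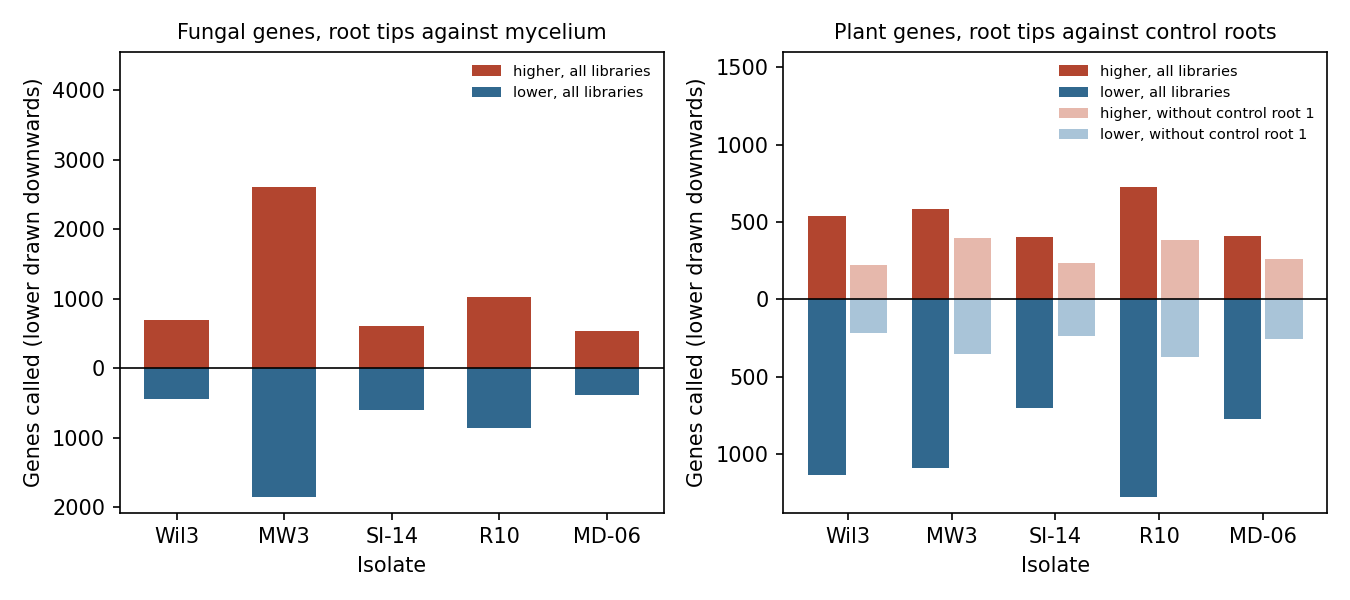
Number of genes called higher (drawn upwards) and lower (drawn downwards) in root tips of each isolate, for the fungus against its free-living mycelium and for the plant against control roots. MW3 has the most fungal calls, 2614 and 1855, and the pale bars show that the plant counts, such as 1276 lower genes with R10, shrink without control root 1, here to 372.

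The isolates were also compared with each other, for differences in fungal expression between isolates that form the same association. The fungal response to the root differed between isolates for 3338 of 10667 genes (edgeR quasi-likelihood test of the interaction, adjusted p under 0.05). Expression differed between the isolates for 8360 genes in free-living mycelium and for 8409 genes in root tips. Isolate accounted for 82.9% of the variance of fungal log2 CPM among root tips, where permuted labels gave 22.2% on average. Over all 34 libraries, isolate within tissue accounted for 74.6% of the variance, and root tip against mycelium within isolate for 16.3%, against 23.9% and 5.92% with permuted labels. Both of these shares include the interaction of isolate and tissue, so they overlap. Without Wil3 they were 83.2% and 11.3%, against 22.4% and 3.77% with permuted labels. Each of these shares had a permutation p of 0.0001, the smallest that these permutations can give. Of the named models, 683137 (adjusted p = 0.029), 199714 (adjusted p = 0.0029) and 4343739 (adjusted p = 0.018) also differed between isolates in their response, and 689733 did not pass that test (adjusted p = 0.84). Reads of all isolates were counted on 1 set of gene models, so a difference between isolates can hold differences in sequence match as well as in expression. With every library thinned to 164614 counts, 683 genes passed the interaction test and 2812 differed between root tips.

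On the plant side, root tips were compared with control roots, averaged over the 5 isolates, for the host response. The titles call the controls roots, so any difference in the part of the root sampled goes with the presence of the fungus. Of 24351 plant genes tested, 1114 were higher and 3109 lower in root tips (edgeR quasi-likelihood test, adjusted p under 0.05). The gene Eucgr.C01882.1 had 0 counts in the 3 control roots and 23.3 ± 22.4 CPM in root tips (SD, n = 19), at least 273-fold above the 0.085 CPM that 3 counts over the control libraries allow (adjusted p = 0.00077), and it passed the test with each of the 5 isolates. Eucgr.L00508.1 also had 0 counts in control roots and stood at 6.60 ± 9.56 CPM in root tips, at least 77.5-fold higher on average (adjusted p = 0.019). It passed the test with 3 of the 5 isolates, and its root tip libraries ran from 0.099 to 38.6 CPM, with those of MW3 between 0.14 and 0.79 CPM. Without control root 1 or 2 its adjusted p was 0.096 and 0.052. Whether fungal reads were counted on this gene or on Eucgr.C01882.1 could not be checked, since the plant table holds no mycelium. Eucgr.B00691.1 fell from 311 ± 506 CPM in control roots (SD, n = 3) to 2.71 ± 2.10 CPM in root tips (log2 fold change -7.13, SE 0.60, adjusted p = 1.43e-06), and each root tip library, at 8.46 CPM or less, lay below the lowest control root, at 17.0 CPM. Eucgr.L01482.1 went from 263 ± 452 CPM in control roots to 10.2 ± 36.0 CPM in root tips (log2 fold change -6.72, SE 1.10, adjusted p = 0.00050), but this rested on control root 1, at 785 CPM. The root tip mean was raised by Wil3 replicate 2, at 158 CPM, with the other 18 root tip libraries at 12.3 CPM or less, and the gene passed the test with 2 isolates. Without control root 1 its log2 fold change was -0.03 (adjusted p = 0.998) and that of Eucgr.B00691.1 was -3.12 (adjusted p = 0.00038).

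Control root 1 stood apart from the other 21 plant libraries. Its Spearman correlation was 0.75 with control root 2 and 0.77 with control root 3, while those libraries correlated at 0.92 with each other, and the lowest value between any other pair was 0.86. The top 1% of genes held 30.4% of its counts, against 21.1% in control root 3 and 19.5% in control root 2. Without it, the average comparison called 457 higher and 744 lower genes, of which 319 and 603 were among the 1114 and 3109 genes of the fit to all libraries. Without control root 2 the counts were 1215 and 3795, and without control root 3 they were 1437 and 3736.

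**Figure D3:**
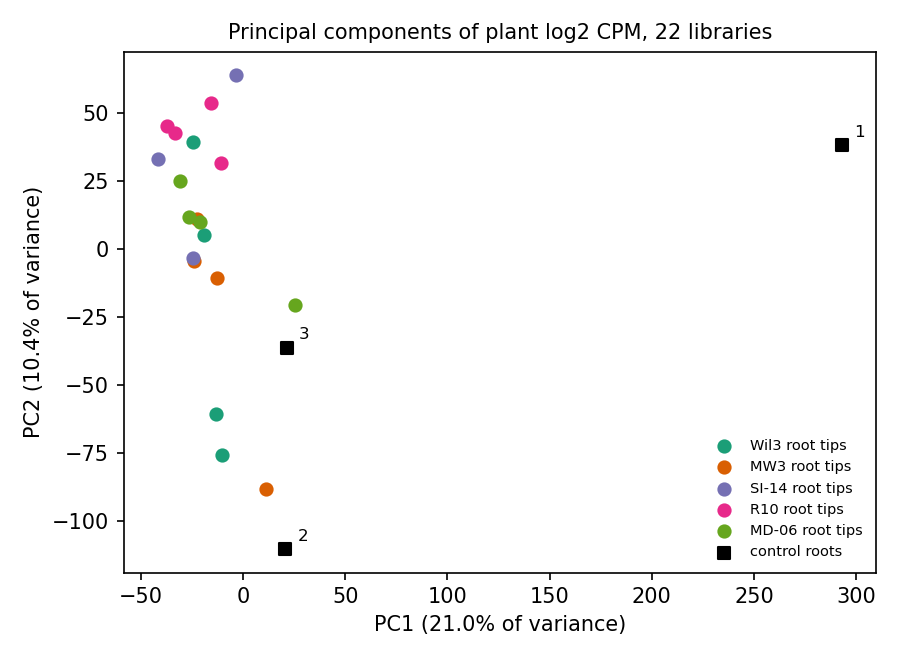
First and second principal components of plant log2 CPM over 22 libraries, with the 3 control roots numbered. Control root 1 lies alone on PC1, which holds 21% of the variance, while control roots 2 and 3, at 20.5 and 21.4, lie above 18 of the 19 root tips on that axis and below the highest of them, at 25.4.

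Plant genes called with single isolates numbered 729 higher and 1276 lower with R10, 537 and 1134 with Wil3, 581 and 1088 with MW3, 410 and 770 with MD-06, and 405 and 704 with SI-14. Genes called with every isolate came to 127 higher and 313 lower. No gene was called higher with one isolate and lower with another. The 5 comparisons share the same control roots, so overlaps and correlations between them lie above chance without any effect. Fold changes of 2 isolates correlated across genes with r of 0.69 to 0.84, 0.78 on average, where 20 simulated data sets without any effect gave 0.57. The mean covariance was 1.53 against 0.41 in the simulations, a difference of 1.12. The simulations gave 0 genes called with every isolate, and independent lists of these sizes would share 0.00011 higher and 0.0024 lower genes. The real lists share control roots, so the figures for independent lists set no level for chance here. In the simulations the average comparison called at most 1 gene. Other splits of the real libraries with control root 1 in the control group called 790 to 2001 genes. The simulations thus did not reproduce what control root 1 yields, and no correlation or covariance without it is given here. The 3 control libraries do not give 2 sets of at least 2, so the controls were not split, and part of the excess may come from sharing them. Without control root 1 the calls fell to 758 with R10, 442 with Wil3, 755 with MW3, 515 with MD-06 and 471 with SI-14, and the genes called with every isolate to 112 higher and 77 lower, 51 and 53 of them in common with the lists above. Higher calls then outnumbered lower ones, as with R10 (386 and 372). Without SI-14 replicate 1 the genes called with every isolate came to 41 higher and 33 lower. Without control root 2 or 3 the calls with single isolates numbered 2471 to 3559, and the genes called with every isolate rose to 215 higher and 1060 lower without control root 2 and to 278 and 974 without control root 3. With DESeq2 they came to 339 and 733. Root tip libraries mattered as well, and the lowest counts were 94 without SI-14 replicate 1, 342 without MD-06 replicate 3, 566 without MW3 replicate 4, 574 without Wil3 replicate 1 and 594 without R10 replicate 3, each for the isolate concerned. Fitted in edgeR with only the 2 groups compared, 12 genes passed with R10, 1 with MD-06 and 0 with Wil3, MW3 or SI-14, where 2691, 2646 and 2389 genes had an unadjusted p under 0.05, while DESeq2 on all libraries called 3375, 3297 and 2889.

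Host expression was also compared between root tips of different isolates, for host differences that go with the isolate. Of 24351 plant genes, 5 differed (edgeR quasi-likelihood test, adjusted p under 0.05), while 1839 had an unadjusted p under 0.05 and DESeq2 called 516. Among the 5, chosen here after their values were seen, Eucgr.B02368.1 stood at 5.15 ± 1.39 CPM with MW3 (SD, n = 4) and at group means of 30.8 to 55.3 CPM with the other isolates (adjusted p = 0.018). Eucgr.B02801.1 was highest with MW3, at 100.9 ± 27.9 CPM (SD, n = 4), against means of 15.5 to 28.5 CPM elsewhere (adjusted p = 0.037). Eucgr.B03804.1 and Eucgr.B03805.1 (adjusted p = 0.037 each) were close to absent with SI-14, at 0.041 and 0 CPM on average over 3 libraries, and stood at means of 9.26 to 18.5 and 2.12 to 3.82 CPM with the others. Eucgr.H02264.1 (adjusted p = 0.037) had means of 34.6 CPM with Wil3, 47.9 with MW3, 98.7 with SI-14, 113 with R10 and 205 with MD-06, where its libraries ran from 73.6 to 306 CPM. Isolate accounted for 25.6% of the variance of plant log2 CPM among root tips, against 22.2% with permuted labels (permutation p = 0.038). This p ranged from 0.0026 to 0.262 when 1 library was left out, and the count of genes from 0 without MW3 replicate 1 or MD-06 replicate 4 to 42 without MD-06 replicate 2. Without control root 1 it was 21. On data simulated for this comparison with genes changed with MW3 alone, 44% of 4-fold and 6% of 2-fold changes were recovered among 24351 genes.

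**Figure D4:**
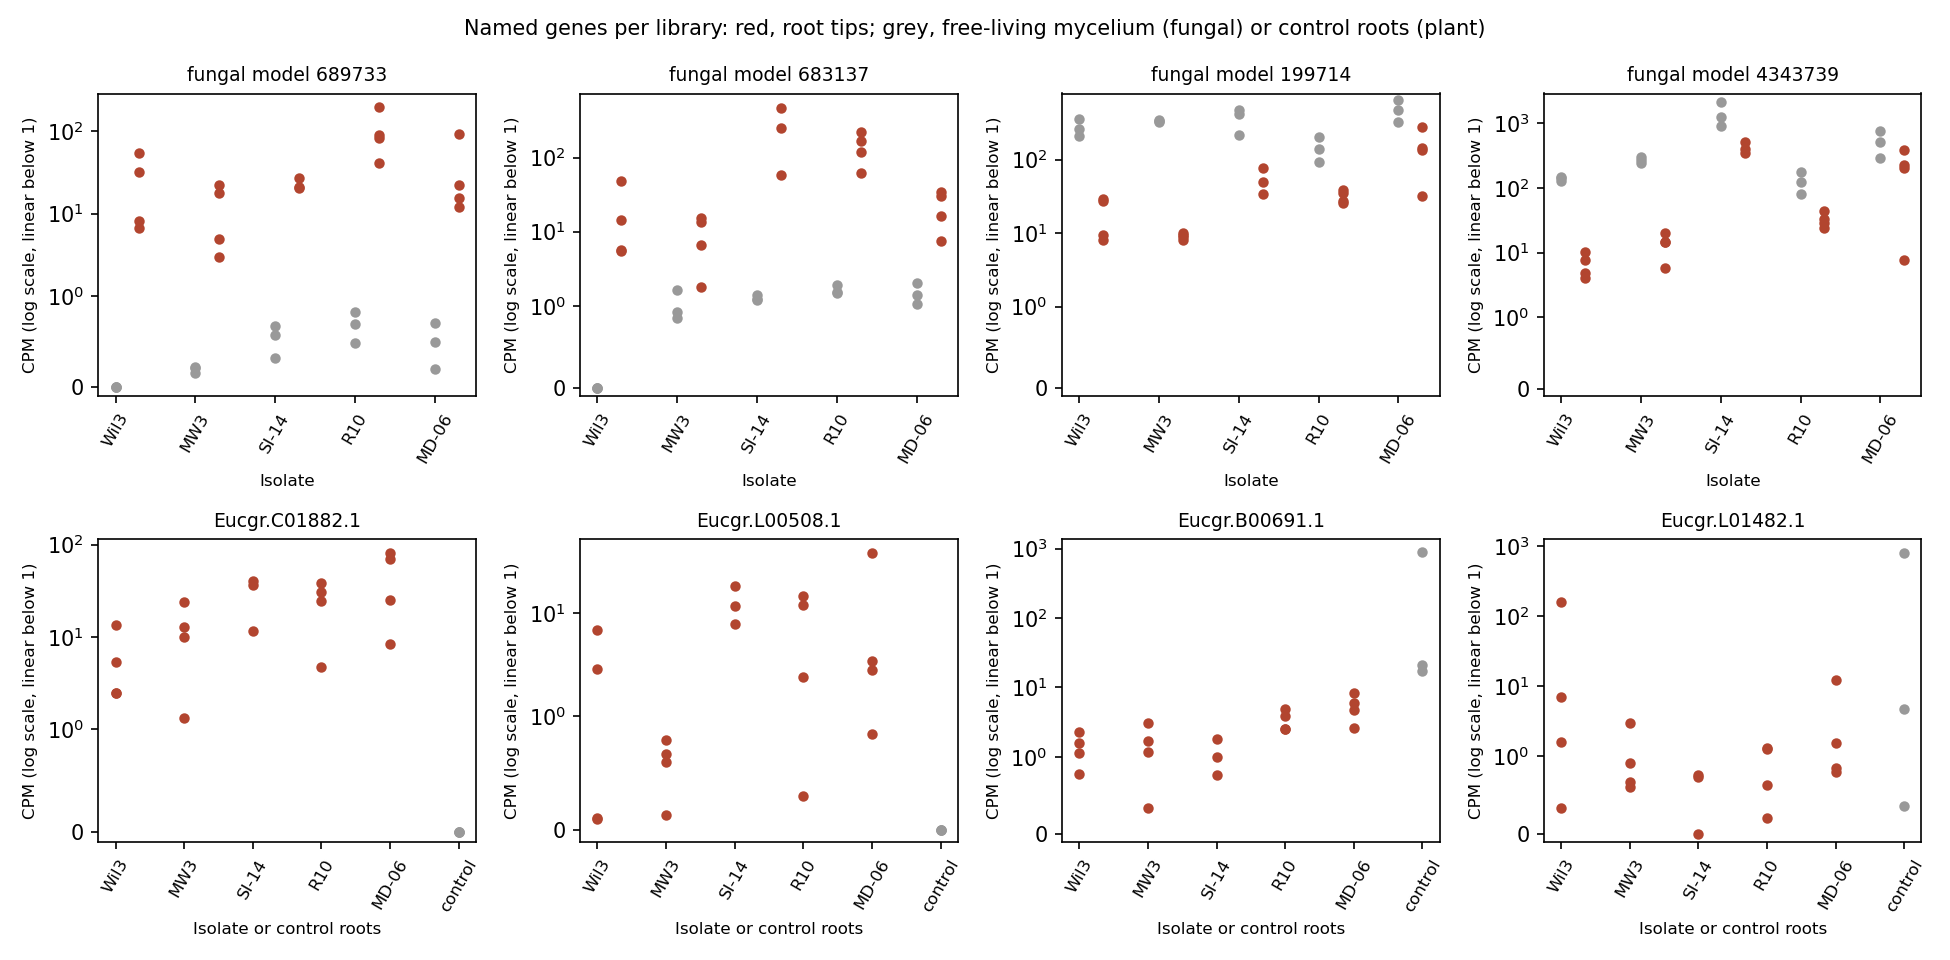
CPM of the 4 fungal and 4 plant genes named by rule, per library, on a scale that is logarithmic above 1 CPM. Red points are root tips and grey points are mycelium or control roots, and the single high control point of Eucgr.L01482.1, at 785 CPM, is control root 1.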

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

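The tests of the spread of the Wil3 response, and the test of a few genes taking most of the counts of control root 1, were chosen after the results were seen, and the bounds of the other tests were set before their results were seen. One pattern concerns control root 1. Its median Spearman correlation with the other plant libraries was 0.742, and the lowest value among the others was 0.864. A few genes taking most of the counts is argued against as the whole source: with the 266 genes of its top 1% removed from every library before scaling, 1100 genes at a median of 10 CPM or more elsewhere lay under 10% of that median in control root 1, against at most 177 in any other library. That test replaced one on rank correlations, which hardly respond to a few genes. Loss of transcripts may account for part of it: 15 genes at 10 CPM or more in every other library had 0 counts there, where no other library lacked more than 1. Genes that this root did not express would give the same result. That test therefore does not tell loss of transcripts from another tissue or plant state. Another tissue or plant state stays open, since 15 genes reached 10 CPM in this library and stayed under 1 CPM in every other, against 5 for the next library, between the bounds set for that test, and no other biological explanation was tested.

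A further pattern is the spread of the fungal fold changes in Wil3, with an SD of 2.05 over genes against 0.654 to 1.03 in the other isolates. Its ratio to the mean SD of the others was 2.67 over 10667 genes and 1.36 with all reads over the 6713 genes that passed the filter when every library was thinned to 164614 counts. In those thinned libraries it was 1.06, so most of the fall went with the genes tested. Over the 6713 genes Wil3 no longer stood apart from MW3, with SDs of 0.964 and 0.959 with all reads and 0.787 and 0.956 thinned. With the mycelium of 1 other isolate at a time thinned to the Wil3 totals and the 10667 genes kept, the SD of that isolate rose to between 1.51 and 1.81, a ratio of 1.96 to 2.72 to the remaining isolates without Wil3, where it was 0.813 to 1.52 before thinning. Lower mycelium depth thus widened the spread in each of these isolates. The bound set for depth as the source was 2 in each isolate, which R10 (1.963) and MD-06 (1.995) did not reach. Whether depth accounts for the whole of the Wil3 spread therefore stays open. The test with 1 isolate thinned at a time replaced the ratio in thinned libraries, which changed depth and genes together. Reads of an equal mix of the other isolates making up 10% or more of these libraries are argued against. Of 32 gene models at 0 in the Wil3 root tips and abundant in the mycelium of the other isolates, 15.6% had a count in the Wil3 mycelium, where a share of 10% would give 71.2%. A share of 1% would give 16.8% and stays open. Reads from a single other isolate were not tested. An earlier form of that test, the level of those models as a percent of the other isolates' level, gave 5.94% with 82.4% of the counts in 1 model, did not decide, and was replaced after its result was seen.

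Tests of the difference itself separated isolates for the 3338 fungal genes of the interaction test and for the 5 plant genes that differed between root tips. From the calls in single isolates, 411 fungal genes were higher in 1 isolate and lower in another, and how many of them are among the 3338 was not counted. Among the named fungal models the adjusted p of the difference was 0.029047 for 683137, 0.0028808 for 199714 and 0.017701 for 4343739 (edgeR quasi-likelihood test). Single libraries far from the rest of their group of 4 were the plant total of R10 replicate 1 (9778810 counts), the model 689733 in MD-06 replicate 2 (93.714 CPM), Eucgr.L00508.1 in MD-06 replicate 2 (38.596 CPM), and Eucgr.L01482.1 in Wil3 replicate 2 (158.36 CPM), MW3 replicate 3 (2.9615 CPM) and MD-06 replicate 1 (12.349 CPM). These were 6 of 44 groups tested, and chance gives about 1 in 20.

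Other splits of the same libraries into groups of the same sizes were refitted, with the real split counted among them. For the fungal average comparison 1 of 100 splits gave as many genes (4257, highest other 54), and likewise 1 of 100 for isolates as mycelium (8360, highest other 3118), for isolates in root tips (8409, highest other 2874) and for genes called the same way in every isolate (89, highest other 0). The interaction also had 1 of 100 (3338, highest other 524), but its splits mixed isolates within each tissue. Differences between isolates then entered the spread within groups, so these splits cannot tell whether the interaction calls exceed chance. In single isolates the share was 1 of 35 splits for MW3 (4469, highest other 2996) and for R10 (1881, highest other 688). That is the smallest share that 35 splits can give, under the bound of 0.05 without adjustment over isolates. The bound was not met for Wil3, with 4 of 35 (1148, highest other 1318), or for MD-06, with 2 of 35 (918, highest other 1047). For SI-14 the 10 splits are too few for a share under 0.05 (1 split, 1202, highest other 1).

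For the plant, 1 of 100 splits gave as many genes in the average comparison (4223, highest other 2001), which does not exclude chance. The 10 other splits that kept control root 1 in the control group called 790 to 2001 genes and the 89 without it there at most 41, so that library yields many calls in groupings that are not the real one, and without it the real grouping called 1201. Only splits with control root 1 in that group are comparable, and the 10 others are too few for a share under 0.05. For genes called the same way with every isolate, 1 of the same 100 splits gave as many (440, highest other 1), with the same limit. The share was 1 of 35 for Wil3 (1671, highest other 122), MW3 (1669, highest other 1374) and R10 (2005, highest other 6). That is the smallest share that 35 splits can give. Here too, only splits with control root 1 in the control group are comparable. They are too few for a share under 0.05, so chance is not excluded for these isolates. The bound was not met for MD-06, where 2 of 35 splits gave as many genes (1180, highest other 1198), and the other split kept control root 1 with 1 more control root in the control group. For SI-14 the 10 splits are too few (1 split, 1109, highest other 0). For root tips of different isolates 2 of 100 splits gave as many genes as the 5 observed, and the other gave 229, several times the real count. Such a split points to a structure of the samples, but it was 1 split, and what sets it apart was not examined.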

How the results depend on the processing

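Leaving out the isolate Wil3, and the alternatives for genes called in every isolate, for variance shares and for undetected gene models, were chosen after the data were seen, and the others before the data were examined. No average fold change of a named gene changed sign under the alternatives that gave it, but the balance of higher and lower calls turned over in several. Fits to only the 2 groups compared gave no average fold change. DESeq2's size factors in edgeR, no low-count filter and a minimum mean count of 10 moved no count of genes by over 1.5 times. Where a count moved, the cause was not tested, except that thinning leaves fewer counts, leaving out libraries leaves fewer samples and a fold minimum removes small changes by construction. In the orders below, isolates run Wil3, MW3, SI-14, R10, MD-06.

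For the fungus, a log2 fold change of at least 1 left 666, 1929, 478, 687 and 366 genes in single isolates, 635 on average, 5278 between root tips of different isolates and 10 lower in every isolate. Thinning to 164614 counts left 551, 1410, 340, 432 and 152 genes, 1709 on average, 683 in the interaction, 2812 between root tips, and 22 higher and 1 lower in every isolate. Without Wil3 the genes called in every isolate were 134 higher and 148 lower. With only the 2 groups compared, 183 genes passed in Wil3, 1925 in SI-14 and 3463 in R10. DESeq2 called 1485 in MD-06. More fungal genes were called lower than higher, against the balance in the report, on average when thinned (828 higher, 881 lower) and, as given above, for genes called in every isolate when Wil3 was left out. In single isolates this held in MW3, SI-14 and R10 when thinned (643 and 767, 153 and 187, 178 and 254), in all 5 with only the 2 groups compared (86 and 97, 2055 and 2164, 904 and 1021, 1639 and 1824, 349 and 392), and in Wil3 and SI-14 with DESeq2 (548 and 645, 852 and 877). It also held in SI-14 with DESeq2's size factors (597 and 606), and in SI-14 and R10 with no filter (521 and 670, 903 and 942) or a mean count of 10 (542 and 676, 912 and 935). Splits of fungal calls by direction were not tabulated with single libraries left out, except for genes called in every isolate. Thinning left 6713 genes to test.

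For the plant, DESeq2 called 3375, 3297, 2889, 3890 and 2846 genes with single isolates, 516 between isolates, and 339 higher and 733 lower with every isolate, and gave no adjusted p for Eucgr.B00691.1 and Eucgr.L01482.1. With only the 2 groups compared, 0, 0, 0, 12 and 1 genes passed in edgeR, and 2691, 2646, 2389, 3472 and 2438 had an unadjusted p under 0.05. Higher plant calls outnumbered lower ones in that fit with R10 (7 and 5) and MD-06 (1 and 0), without control root 1 with each isolate (223 and 219, 400 and 355, 237 and 234, 386 and 372, 262 and 253) and for genes called with every isolate (112 and 77), and for the latter without SI-14 root tip replicate 1 (41 and 33).

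The replicate numbers do not pair the samples, as same-numbered deviations correlated from -0.115 to 0.175 in the fungal and from -0.279 to 0.207 in the plant table. With the title number as a replicate block the plant counts were 447, 635, 436, 921 and 460, 2434 on average, 0 between isolates (1441 at an unadjusted p under 0.05 in edgeR), and 57 higher and 94 lower with every isolate. With the description number as the block they were 563, 675, 582, 1061 and 568, 2618 on average, 0 between isolates (1486 unadjusted), and 69 and 105. Under these blocks the adjusted p of Eucgr.L01482.1 was 0.0805 and 0.0819, and no fungal count moved by over 1.5 times.

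Leaving out 1 library at a time, the fungal counts ranged from 667 to 1623 in Wil3, 3629 to 4699 in MW3, 494 to 1554 in SI-14, 1026 to 2294 in R10, 465 to 1273 in MD-06, 3820 to 4369 on average and 17 to 44 for genes lower in every isolate. The plant counts ranged from 442 to 3105 with Wil3, 566 to 2903 with MW3, 94 to 2545 with SI-14, 594 to 3559 with R10, 342 to 2529 with MD-06, 1201 to 5173 on average, 0 to 42 between isolates, and 41 to 278 higher and 33 to 1060 lower with every isolate. The permutation p of the plant variance between isolates ranged from 0.0026 to 0.262 and was above 0.05 without each of 11 libraries in turn. Depth limits the root tip comparison of Wil3, where 42% of simulated 2-fold changes were recovered against 69% in MW3.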

Other observations

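The tests in this part were all chosen after the data were seen. Isolate differences in fungal expression carried over from mycelium to root tips. Across 10667 genes, which are not independent replicates, the deviation of an isolate from the mean of the isolates in mycelium correlated with its deviation in root tips at r = 0.90 for MD-06, 0.87 for SI-14, 0.85 for R10, 0.74 for MW3 and 0.53 for Wil3. Differences in how well reads of an isolate match the gene models would also carry over in this way, and no test here separates them from expression. The Wil3 mycelium was far shallower, which can add counting noise to its deviation and to the mean. The value of Wil3 is therefore not comparable with the others. With Wil3 left out, r was 0.92 for MD-06, 0.92 for SI-14, 0.89 for R10 and 0.76 for MW3.

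Some gene models had 0 counts in every library of an isolate while another isolate reached a mean of 1 CPM. There were 297 such models for SI-14, 291 for Wil3, 258 for MD-06, 245 for MW3 and 155 for R10, where 3 counts over an isolate's libraries allow 0.043 to 0.152 CPM. With a mean of 10 CPM required elsewhere the numbers were 117, 103, 79, 84 and 48, and with up to 3 counts allowed 404, 415, 396, 359 and 239, so the order of the isolates changed with the threshold. Detected in a single isolate were 33 models for R10, 24 for MW3, 15 for MD-06 and 12 each for SI-14 and Wil3, with 5, 7, 3, 1 and 1 when a mean of 10 CPM was required and 67, 39, 33, 28 and 31 with up to 3 counts allowed. These counts do not tell absent genes from genes whose sequence the reads do not match or genes that were not expressed.

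A hypothesis was that root tip libraries which depart in plant profile from their isolate also depart in fungal profile. Over 19 libraries, with each isolate centred, the first components of the plant table (16.5% of the variance) and of the fungal table (21.3%) correlated with Pearson's r = 0.72 (permutation p = 0.039) and Spearman's rho = 0.74 (permutation p = 0.017). Over the 3 relations computed the Benjamini-Hochberg adjusted p was 0.117 and 0.051, so the relation did not pass after adjustment. At a fixed fungal share of counts r was 0.69, and with 1 library left out at a time it ran from 0.446 without Wil3 replicate 2 to 0.881 without Wil3 replicate 1, on both sides of the bound of 0.5. The amount of fungal tissue therefore stays open as a source, and the share is one of counted reads, not of tissue mass. Without Wil3 replicate 2 the plain r was 0.43. Without the 2 libraries farthest from the median of the plant component, Wil3 replicate 1 and MD-06 replicate 2, the answer depended on the axis. On the first components, whose axes those 2 libraries helped to set, r was 0.60 with the first centres and 0.56 with the isolates centred again. With the components fitted again as well, r was 0.38, between the bounds set for that test, and -0.12 over the isolates other than Wil3. The plant component was then largely another axis, with loadings that correlated at 0.22 with those of the first fit, against 0.56 for the fungal component. Whether the relation rests on those 2 libraries stays open. The form with the first centres was the first one run, and the others were added after its result was seen. Within isolates r was -0.52 in SI-14, 0.17 in R10, 0.43 in MW3, 0.65 in Wil3 and 0.98 in MD-06, over 3 or 4 libraries each.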
